A study of Homo sapiens with 8 samples.

How the data were processed

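Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in MCF-7 cells, an estrogen-receptor-positive breast cancer line, in 8 libraries. Each library was a group of its own: 2 antibodies (ER and SRC-3), control or shFbxo22 cells, and E2 alone or E2+4OHT. Per the labels' protocols, chromatin was prepared with an enzymatic chromatin immunoprecipitation kit, libraries were made with an Ion Xpress Plus fragment kit, and cells received 100 nM E2 and, where stated, 10 nM 4OHT for 2 h. Groups were taken from the sample titles. The names of the deposited tables mark the samples titled control with the gene's name and those titled shFbxo22 as without it, and the titles were followed. Whether any cells were exchanged between titles cannot be checked from the files, and an exchange would invert every ratio of shFbxo22 over control and swap the 4OHT ratios between the 2 cell types. No replicate, input or control-antibody library is among the samples.

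The deposited files are 8 peak tables, 1 per library, made with HOMER on hg19 per the submitters' processing notes. Peaks were listed per library. The aligner, the peak-calling settings, the input used and any filter on the peaks are not stated. The deposited peak score is the authors' value on the scale of its own list. It ranked peaks within a list, chose the window of each merged ER site across lists, and described the lists. The deposited signal values are tags in a 50 bp window around the peak centre, scaled by the authors to 10 M tags per library, per the file headers. Each table gives this signal for all 8 libraries at its own peaks. The GC share in the deposited tables is a fraction of the window's bases, per the file headers, and was not used in a comparison. The tables of 7 libraries also mark matches of HOMER's estrogen response element (ERE) in the window, and the table of SRC-3 peaks of control cells with E2+4OHT does not. Every listed peak spans 51 bp, so the original peak widths are not known. Gene names, annotation classes and distances to the transcription start site (TSS) are those of the files.

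Library totals were read from the column headers and ranged from 28.1 to 39.2 M tags (M, mega), a ratio of 1.40. Multiplying each scaled value by its library's total gave whole reads for 100% of values, within 0.005 tags per 10 M. The counts recovered this way give each ratio its counting precision. A count model with a spread between replicates could not be fitted, because every group has 1 library. No p-value is given for any difference between conditions. All intervals are at 95% and, for the same reason, cover counting error over peaks, sites or tags only. They treat tags and sites as independent. Tags without molecular identifiers are not independent molecules, so the intervals may be too narrow.

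Peaks on chromosomes 1 to 22 and X were used. Peak lists were compared with bedtools 2.31.1, and a peak was shared where it overlapped a peak of the other list by at least 1 bp. Shares carry Wilson intervals. Background was the range over 100 random placements of the first list within chromosomes. A share of the first list in the second is set by the lengths of both lists, so the reverse share and both peak numbers are given beside it.

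For signal, overlapping peaks of the 4 ER lists were merged into 44556 ER sites, and each site took the window and tags of its highest-scoring peak. This choice compared scores across lists, whose scales may differ (median 6.64 in control and 8.34 in shFbxo22 cells with E2). The windows may therefore lean towards libraries with higher scores, and the effect on the ratios was not tested. A site held an ERE where any of its peaks was marked with a match. Sites listed in all 4 ER libraries were called common ER sites. Tags at a set of sites were summarised by the interpolated median of the whole counts, divided by the library total, and ratios of medians carry intervals from 1000 bootstrap draws over sites. Ratios at single sites carry conditional exact (Clopper-Pearson) intervals from the tag counts of both libraries. Such an interval compares those libraries, not the conditions. Each gene was represented by the ER site with the highest mean ER tags within 50 kb of its TSS, which gave 10129 genes with a site. Spearman correlations were computed across sites, which are not independent replicates.

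Of 13328 gene symbols in the files, 12743 (95.6%) matched a symbol or older symbol of the reference gene table, which is of assembly GRCh38.p14 and was used for names only. Gene lists were fixed before the data were examined: estrogen response, luminal transcription factors, ER coregulators, cell cycle, immediate early and AP-1 genes, growth factor signalling, housekeeping, genes of regions amplified in MCF-7 cells, and genes of other lineages. A member counted where it was the nearest gene of a peak within 50 kb of its TSS. Its number was placed as a percentile among 10000 random lists of the same size, drawn from all reference genes and, as additions, from protein-coding genes and from genes nearest to any listed peak. For ratios at sites, the random lists were matched on mean ER signal in 10 classes. The named genes followed a rule fixed at the same time. Per comparison it took the 10 peaks with the highest score among those in both lists and among those in only 1 list, 1 peak per nearest gene. It also took TFF1, GREB1, PGR, MYC, CCND1, XBP1, CTSD, NRIP1, RARA, EBAG9, ESR1, FOXA1, GATA3, NCOA3, KDM4B and FBXO22 always, and up to 4 members per list ordered by the number of libraries with a peak.

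The steps were tested on simulated data with known answers. Simulated lists returned 100% of the 1879 shared peaks put in, and 100% of the 3758 within 500 bp. For ER, shFbxo22 over control under E2, counts were drawn at 12645 sites with 200 changed 3-fold. The intervals called 72.0% of sites raised 3-fold and 42.0% of sites lowered 3-fold, and 2.88% of unchanged sites. For SRC-3, E2+4OHT over E2 in control cells, these shares were 61.0%, 30.0% and 2.43%. These draws held Poisson error only and no library-wide difference, unlike the real libraries. The shares therefore describe the intervals under their own assumptions and are not error rates of the calls per gene. A library-wide factor of 2 was recovered as 1.97 and 2.01.

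The alternatives fixed in advance were 50% reciprocal overlap, midpoints within 500 bp, the upper 50% of each list by score, lists of equal length, omission of dense 1 Mb bins (116 bins with over 5 times a library's median peak number), and other distances to the TSS. The comparisons of signal at ER sites, their alternatives, and the ratios per gene were added after the data were seen. Motif searches were left out because no genome of the files' build was at hand, so only the files' own ERE marks were used. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 1.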

Results

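The series profiled where estrogen receptor alpha (ER) and its coactivator SRC-3 (the product of NCOA3) sat on the genome of MCF-7 cells, and asked how Fbxo22, a substrate receptor of a ubiquitin ligase, affects that recruitment. Cells carried a control construct or a short hairpin RNA against Fbxo22 (shFbxo22). They received the ER ligand estradiol (E2), or E2 with 4-hydroxytamoxifen (4OHT), a selective ER modulator that blocks estrogen action in breast cells. There were 8 libraries, 1 for each antibody, cell type and treatment, so no difference between conditions has a replicate check. Library totals for ER were 39.2 M tags (M, mega) in control cells with E2 and 32.6 M with E2+4OHT, and 32.4 and 37.0 M in shFbxo22 cells. For SRC-3 they were 28.1 and 38.1 M in control cells and 32.1 and 31.0 M in shFbxo22 cells. The files hold no measure of Fbxo22 itself, and neither FBXO22 nor MYC was the nearest gene of a listed peak within 50 kb of its TSS.

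In control cells, 12580 ER peaks were listed with E2 and 26690 with E2+4OHT. In shFbxo22 cells the order was the opposite, with 23173 ER peaks under E2 and 19879 under E2+4OHT. SRC-3 peaks numbered 1721 and 2515 in control cells, and 5570 and 2602 in shFbxo22 cells. Promoters held 2.13% to 3.09% of ER peaks and 3.46% to 5.78% of SRC-3 peaks, while introns held 43.9% to 47.7% and intergenic sequence 40.7% to 49.1% of peaks over the 8 libraries. An ERE was marked in 7.56% (95% Wilson interval 7.11% to 8.03%) of ER peaks in control cells with E2 and in 3.83% (3.61% to 4.07%) with E2+4OHT. In shFbxo22 cells it was marked in 5.96% (5.66% to 6.27%) and 5.34% (5.04% to 5.66%). Among the 1000 ER peaks with the highest score these shares were 26.1%, 18.1%, 24.1% and 20.4%. The SRC-3 list of control cells with E2+4OHT differed from the other 7 in its scores: its highest peak score was 9.71, against 445 to 2366 in the other lists. Its highest own signal at a listed peak was 5.25 tags per 10 M, against 259 or more in the other SRC-3 lists.

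**Figure D1:**
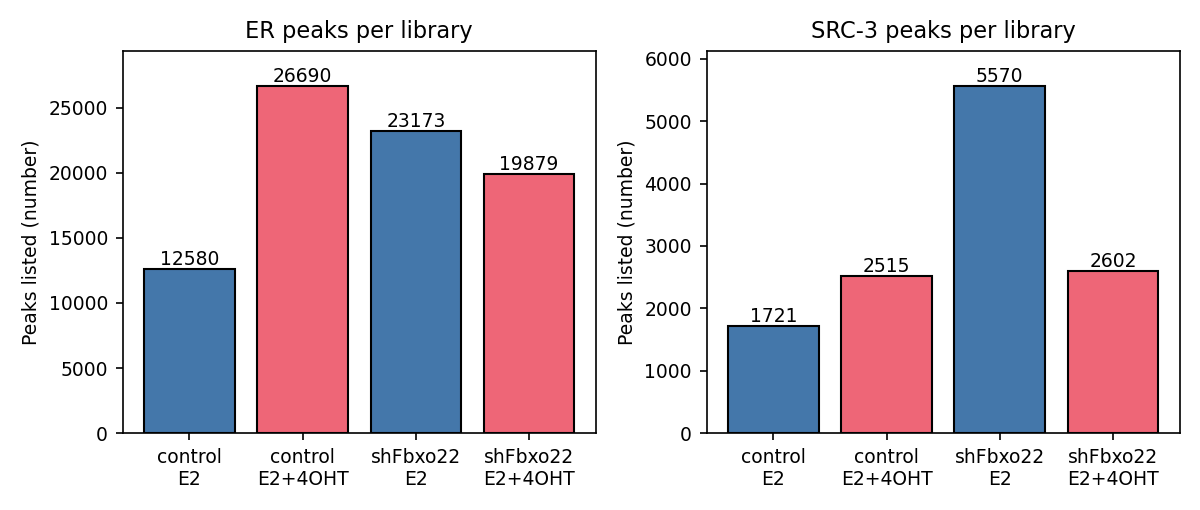
Number of listed peaks on chromosomes 1 to 22 and X in each library, for ER and SRC-3, with E2 in blue and E2+4OHT in red; each bar is 1 library. ER peaks were more numerous with 4OHT in control cells (26690 against 12580) and fewer in shFbxo22 cells (19879 against 23173).

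To ask whether Fbxo22 affects ER binding under estrogen, ER peaks of control and shFbxo22 cells with E2 were compared. Of the control peaks, 65.8% (65.0% to 66.7%) overlapped an shFbxo22 peak, and 35.7% of shFbxo22 peaks overlapped a control peak, with 8283 of these shared. Random placements gave at most 0.151%. The shared peaks with the highest scores in control cells included alpha satellite sequence, which has many near-identical copies in the genome, and sites near PFDN4, NACA2, MIR1208, TEX14 and PARD6B. The PFDN4 site (hg19 chromosome 20, 52812035 to 52812085, intergenic) had 585 ER tags per 10 M in control and 1084 in shFbxo22 cells. The MIR1208 site (chromosome 8, 129154321 to 129154371) had 317 and 678. Of the 10 named peaks found in the control list alone, 7 had a peak of the other list within 500 bp, as did 5 of the 10 found in the shFbxo22 list alone. The former included the intronic DSCAM-AS1 peak (chromosome 21, 41696548 to 41696598; 93.2 and 87.1 ER tags per 10 M in control and shFbxo22 cells). At the 7175 common ER sites, the median ER signal was 2.06 times as high (2.02 to 2.11) in shFbxo22 cells, and 89.9% of sites were higher.

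With 4OHT present, 44.8% (44.2% to 45.4%) of control ER peaks overlapped an shFbxo22 peak, and 60.2% of shFbxo22 peaks overlapped a control peak, against at most 0.109% at random. The ER signal of shFbxo22 cells was lower here, with a ratio of medians of 0.712 (0.699 to 0.724) at common ER sites. Peaks in the control list alone included those near NCOA3 (chromosome 20, 46084105 to 46084155, intergenic) and BMP7. Peaks in the shFbxo22 list alone also included NCOA3 and BMP7 peaks, at positions within 500 bp of the former. Of the 10 named peaks in each class, 5 and 9 had a peak of the other list within 500 bp.

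The second question was how 4OHT acts on ER in either background. In control cells 65.4% (64.6% to 66.2%) of E2 peaks overlapped an E2+4OHT peak, and 30.8% the other way. In shFbxo22 cells these shares were 47.1% (46.4% to 47.7%) and 54.9%. Random placements gave at most 0.223%. Peaks near CT62 (chromosome 15, 71397191 to 71397241) and DSCAM-AS1 were in the E2 list of control cells alone, with 50.3 and 93.2 ER tags per 10 M under E2 and 30.1 and 26.4 under E2+4OHT. A peak near DOK5 (chromosome 20, 53073179 to 53073229) was in the E2+4OHT list alone, with 6.38 and 43.6. In shFbxo22 cells a peak near CYP24A1 (chromosome 20, 52740386 to 52740436) was in the E2 list alone, with 72.0 ER tags under E2 and 20.3 under E2+4OHT. Of the 10 named peaks in the E2 list alone, 6 in control and 7 in shFbxo22 cells had a peak of the other list within 500 bp. For the E2+4OHT list alone these numbers were 2 and 9.

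ER sites were then split by the ERE. Of the 44556 ER sites, 7175 (16.1%) were in all 4 lists, and 16.9% of these held an ERE. Sites found in the list of control cells with E2+4OHT alone numbered 10479, and 1.52% held one. Sites in any other single list also rarely held one: 1.92% for control cells with E2, and 3.08% and 2.28% for shFbxo22 cells with E2 and E2+4OHT. A common site had more windows in which an ERE could be marked, which favours its share. Nearby peaks of other lists that did not overlap also counted as separate sites, so some single-list sites may be shifted windows of shared sites. At the 1214 common sites with an ERE, the ratio of median ER tags, E2+4OHT over E2, was 1.56 (1.45 to 1.64) in control and 0.490 (0.465 to 0.524) in shFbxo22 cells. At the 5961 common sites without an ERE it was 1.93 (1.88 to 1.97) and 0.677 (0.661 to 0.694). The ratio at ERE sites was thus 0.807 (0.750 to 0.853) of that at other sites in control cells and 0.724 (0.687 to 0.774) in shFbxo22 cells. For shFbxo22 over control it was 1.02 (0.970 to 1.08) under E2 and 0.918 (0.877 to 0.988) under E2+4OHT. The ratio of shFbxo22 over control under E2 was not the same at all sites. Without an ERE it was 1.85, 2.09 and 2.17 from the class with the weakest to that with the strongest ER signal. At the 374 ER sites in satellite sequence it was 0.880 (0.762 to 1.07). In 3 classes of sites by mean ER signal, the 4OHT ratio in control cells was 1.52, 1.67 and 1.54 with an ERE, and 1.80, 1.99 and 1.79 without, from the weakest to the strongest class.

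**Figure D2:**
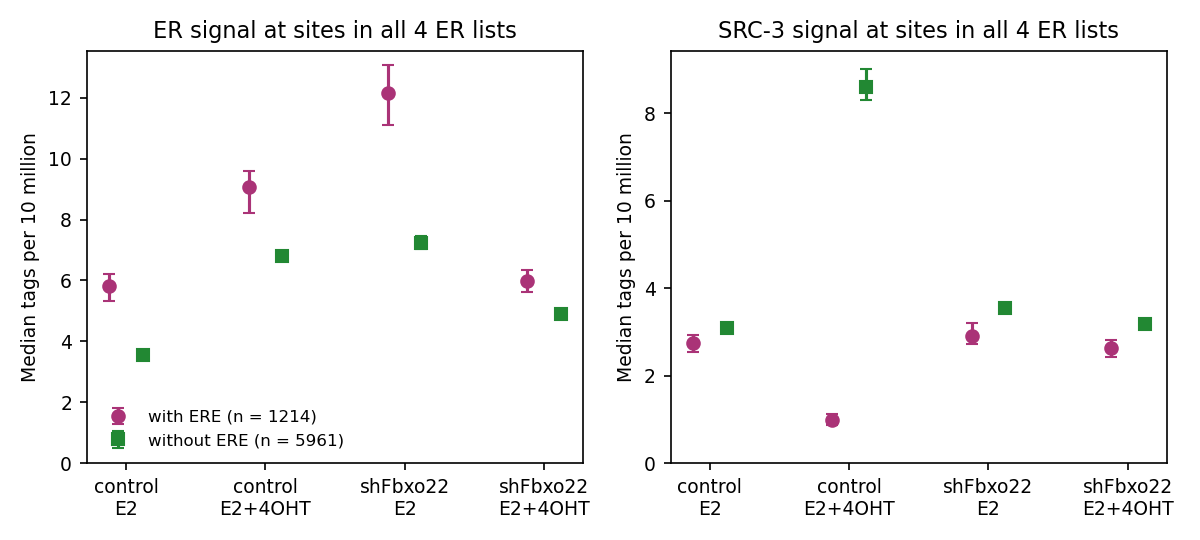
Median ER and SRC-3 tags per 10 M at common ER sites, with an ERE (circles, 1214 sites) and without (squares, 5961 sites), in each library; bars are 95% bootstrap intervals over sites. SRC-3 in control cells with E2+4OHT had a median of 0.979 with an ERE and 8.60 without, while the other SRC-3 medians lay between 2.63 and 3.55.

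For SRC-3 under E2, 22.4% (20.5% to 24.4%) of the control peaks overlapped an shFbxo22 peak and 6.91% of the shFbxo22 peaks overlapped a control peak, with 385 shared. The strongest shared peaks lay near PFDN4, MIR1208, TEX14 and PREX1. At the PFDN4 peak (chromosome 20, 52812047 to 52812097) SRC-3 had 259 tags per 10 M in control and 323 in shFbxo22 cells, and at the PREX1 peak (chromosome 20, 47481457 to 47481507) 59.5 and 85.9. Some peaks named from 1 list alone had a like or higher signal in the other library. The ADCY9 peak (chromosome 16, 4202447 to 4202497), in the shFbxo22 list alone, had 35.6 tags in control and 43.6 in shFbxo22 cells. The ESR1 peak (chromosome 6, 151985658 to 151985708), in the control list alone, had 16.8 and 27.4. At common ER sites the ratio of median SRC-3 tags, shFbxo22 over control, was 1.06 (0.999 to 1.14) with an ERE and 1.15 (1.12 to 1.18) without.

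SRC-3 peaks lay on ER peaks of the same condition in 35.2% (33.0% to 37.5%) of cases in control cells with E2, 13.0% (12.1% to 13.9%) in shFbxo22 cells with E2, and 19.9% (18.4% to 21.5%) in shFbxo22 cells with E2+4OHT. In control cells with E2+4OHT the share was 0.636% (0.392% to 1.03%), 16 of 2515 peaks. Random placements gave at most 0.278% for these 4 pairs. Of the 500 SRC-3 peaks with the highest score in each list, 83.4%, 86.4%, 71.4% and 0.8% lay on ER peaks, in the same order. Against the ER lists of the other 3 conditions, the SRC-3 peaks of control cells with E2 overlapped in 28.9% to 35.9% and those of control cells with E2+4OHT in 0.318% to 0.716%. The ranges were 10.2% to 11.6% for shFbxo22 cells with E2 and 21.2% to 22.8% with E2+4OHT. The low shares of control cells with E2+4OHT do not show that SRC-3 signal was absent from ER sites. That library's own list held 1 of its 13382 ER sites with at least 5 SRC-3 tags per 10 M. Its mean SRC-3 signal at all ER sites was 6.11 tags per 10 M, against 1.76 to 2.01 in the other SRC-3 libraries.

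SRC-3 was then compared between E2 and E2+4OHT. Of the SRC-3 peaks of control cells with E2, 9 (0.523%, 0.275% to 0.991%) overlapped a peak of the E2+4OHT list. In shFbxo22 cells 462 (8.29%, 7.60% to 9.05%) did, which was 17.8% of the E2+4OHT list. Between control and shFbxo22 cells with E2+4OHT, 2 peaks were shared, near CCR6 and TMEM160. The peaks named next come from the E2 list of control cells. That list held 72.8% of the ER sites with at least 5 own tags per 10 M where the control library with E2+4OHT was under 0.25 of the own signal. It held 0.223% of those where that library was at least as high, so a low signal there goes in part with being listed. At the PREX1 peak the SRC-3 signal was 59.5 with E2 and 1.84 with E2+4OHT in control cells, and 85.9 and 64.6 in shFbxo22 cells. At the E2F6 peak (chromosome 2, 11638845 to 11638895) it was 54.2 and 1.05 in control cells, and 37.1 and 39.1 in shFbxo22 cells. The peaks of the E2+4OHT list of control cells, led by TRIM36 and ARHGAP42, had under 5 SRC-3 tags per 10 M each among the 10 named.

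At common ER sites with an ERE, the median SRC-3 signal of control cells was 2.74 tags per 10 M with E2 and 0.979 with E2+4OHT, a ratio of 0.357 (0.316 to 0.413; ratio of means 0.650), and 71.2% (68.6% to 73.6%) of the sites were lower. In shFbxo22 cells the medians were 2.91 and 2.63, a ratio of 0.904 (0.839 to 0.962), and 56.4% of sites were lower. With E2+4OHT, the median SRC-3 signal of shFbxo22 cells at these sites was 2.69 times (2.35 to 3.05) that of control cells, and the mean was 1.44 times. At common ER sites without an ERE the control ratio went the other way, at 2.78 (2.68 to 2.90), and the shFbxo22 ratio was 0.896 (0.870 to 0.919). In the 3 classes of ER strength, the control ratio at ERE sites was 0.567, 0.356 and 0.265 from the weakest to the strongest class, and 2.97, 3.20 and 2.07 without an ERE. Across common ER sites, the SRC-3 library of control cells with E2+4OHT had Spearman correlations of 0.465 to 0.499 with the other 3 SRC-3 libraries, which correlated with each other at 0.776 to 0.804. Its correlations with the ER libraries were 0.123 to 0.319. Among its 12 highest signals at ER sites, chosen after their values were seen, were sites near SUMO1P1 (chromosome 20, 52482920 to 52482970; 1205 SRC-3 tags per 10 M, against 82.0 to 106 in the other SRC-3 libraries) and MIR21 (chromosome 17, 57914811 to 57914861; 598 against 94.3 to 125). Neither of these sites held an ERE, and neither was in the SRC-3 list of that library. Others of the 12 lay near NCOA3, DOK5, BCAS1 and USP32, which are on the list of genes of amplified regions. The SUMO1P1 site itself lies between the strongest ER sites of ZNF217 and BCAS1. The MIR21 site lies between those of VMP1 and TUBD1, and all of these genes are on that list too. Tags were not corrected for copy number, as no input was available. Of 13382 ER sites with at least 5 tags per 10 M in this SRC-3 library, 1 lay within 500 bp of a peak of its own list. The other SRC-3 lists also lacked most of their own such sites. They held 264 of 2692 (9.81%) in control cells with E2. In shFbxo22 cells they held 336 of 3428 (9.80%) with E2 and 264 of 2902 (9.10%) with E2+4OHT.

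Among the genes fixed in advance, GREB1, TFF1, CTSD and RARA were the nearest gene of a peak within 50 kb in 4 ER and 3 SRC-3 lists, with none in the SRC-3 list of control cells with E2+4OHT. CCND1 and KDM4B had peaks in 4 ER and 2 SRC-3 lists, as did GATA3, whose SRC-3 peaks were in control cells with E2+4OHT and shFbxo22 cells with E2. ESR1, FOXA1 and EBAG9 had peaks in 4 ER and 1 SRC-3 list, XBP1 and NCOA3 in 4 ER lists only, and PGR and NRIP1 in 3 ER lists only. A missing SRC-3 peak does not show that SRC-3 signal was absent. Over the SRC-3 libraries, the strongest ER site had 16.0 to 36.7 SRC-3 tags per 10 M at XBP1 and 62.6 to 253.6 at NCOA3. At the GREB1 promoter (chromosome 2, 11679787 to 11679837, 268 bp upstream of the TSS, with an ERE), ER signal was 57.5 and 77.1 tags per 10 M in control cells with E2 and E2+4OHT, and 120.1 and 71.9 in shFbxo22 cells. SRC-3 there was 27.8 and 0.79 in control cells, a ratio of 0.0283 (0.00572 to 0.0859) from 78 and 3 tags. In shFbxo22 cells it was 25.2 and 13.9, a ratio of 0.550 (0.371 to 0.806). At CTSD (chromosome 11, 1817930 to 1817980, intergenic) the SRC-3 ratio, E2+4OHT over E2, was 0.273 (0.155 to 0.463) in control and 1.18 (0.771 to 1.80) in shFbxo22 cells. At RARA (chromosome 17, 38478720 to 38478770, intron, with an ERE) it was 0.123 (0.0133 to 0.551) and 1.32 (0.684 to 2.61), from 2 and 12 tags in control cells. At XBP1 (chromosome 22, 29209862 to 29209912, intergenic, with an ERE) it was 0.599 (0.420 to 0.851) and 0.8 (0.601 to 1.06).

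The pattern was not shared by every gene. At the TFF1 promoter (chromosome 21, 43786826 to 43786876) the SRC-3 ratio was 1.27 (0.837 to 1.96) in control and 1.11 (0.718 to 1.71) in shFbxo22 cells, so no difference was detectable at this depth. At the ESR1 site (chromosome 6, 151979367 to 151979417, intergenic, with an ERE) SRC-3 was higher with 4OHT, at 1.71 (1.39 to 2.12) and 1.43 (1.04 to 1.99). At FOXA1, GATA3 and NCOA3 the control ratio was 4.54, 2.44 and 3.73, while the shFbxo22 intervals spanned 1. The KDM4B intronic site (chromosome 19, 4991741 to 4991791) had SRC-3 ratios of 1.19 (0.805 to 1.77) and 0.997 (0.662 to 1.499). SRC-3 at CCND1, PGR, NRIP1 and EBAG9 had at most 11 tags in any library. At CCND1 the SRC-3 ratio in control cells was 0.164 (0.0172 to 0.791) from 2 and 9 tags, and the intervals of the other 3 genes spanned 1.

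**Figure D3:**
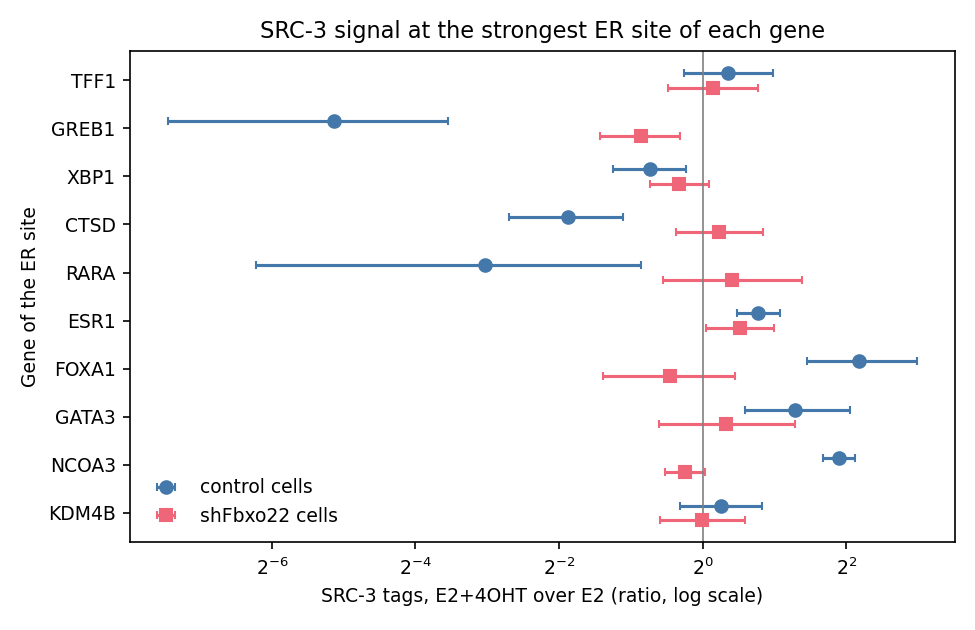
Ratio of SRC-3 tags, E2+4OHT over E2, at the strongest ER site of each gene fixed in advance with at least 10 SRC-3 tags under E2 (log axis), in control cells (circles) and shFbxo22 cells (squares); bars are 95% conditional exact intervals for the libraries. GREB1, CTSD and RARA lay at 0.0283, 0.273 and 0.123 in control cells and at 0.550, 1.18 and 1.32 in shFbxo22 cells.

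Of the estrogen response list, these numbers of members were near ER peaks: 32 of 40 in control cells with E2, 35 with E2+4OHT, and 35 and 34 in shFbxo22 cells. Near SRC-3 peaks it had 18 and 2 in control cells and 23 and 17 in shFbxo22 cells. All these numbers were at percentile 100 of random lists from all reference genes, except the 2 of the SRC-3 list of control cells with E2+4OHT. These were at percentile 87.4, at 56.6 among protein-coding genes and at 16.2 among genes nearest to any listed peak. That list lacks 13381 of the 13382 ER sites with at least 5 own tags per 10 M. The other SRC-3 lists held 65.6% to 72.8% of their own such sites where that library was under 0.25 of the own signal. Where it was at least as high they held 0.223% to 0.537%. A missing peak in any SRC-3 list therefore does not show that SRC-3 signal was absent. The SRC-3 counts and percentiles of all gene lists in this paragraph may partly reflect which sites were listed. ADCY9, ABCA3, CELSR2 and CTSD led the list by number of libraries. Among luminal transcription factors, led by TFAP2C, GRHL2, SPDEF and GATA3, 14 to 19 of 20 had an ER peak and 4 to 8 an SRC-3 peak. The share of this list near ER peaks was 95% against 87.5% of the estrogen response list in control cells with E2+4OHT, and 70% against 80% with E2. Luminal, growth factor and amplified-region lists were also at percentile 100 of all reference genes in all 4 ER lists. For these ER lists among genes nearest to any listed peak, the amplified-region list was at percentiles 60.8 to 91.8. The growth factor list was at 70.2 to 99.2, the luminal list at 99.8 to 99.96, and the estrogen response list at 99.99 or higher. Against all reference genes, housekeeping genes were at percentile 100 for SRC-3 with E2 in both cell types. For genes of amplified regions, led by PFDN4, PREX1, CYP24A1 and EYA2, the numbers were 11 to 19 and 1 to 5 of 25. For growth factor signalling, led by SGK3, ERBB4, GAB2 and AREG, they were 12 to 18 and 2 to 7 of 22. Immediate early and AP-1 genes, led by EGR3, FOSL2, IER3 and KLF10, had 9 to 11 and 2 to 11 of 20. ER coregulators, led by KDM4B, NCOR2, CARM1 and CREBBP, had 5 to 10 and 0 to 3 of 20. Housekeeping genes, led by GAPDH, HSPA8, YWHAZ and GUSB, had 5 to 7 and 0 to 9 of 20. Cell-cycle genes, led by CCND1, CDKN1A, E2F2 and CCNE2, had 4 to 8 and 0 to 5 of 24. Genes of other lineages, led by CD3E, RHO, HBA1 and APOA1, had 2 to 7 and 0 to 1 of 26.

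At the strongest ER site of each estrogen response gene (35 had one), SRC-3 in control cells was lower with E2+4OHT than with E2 at 17 genes and higher at 6, by intervals that excluded 1. Random lists matched on ER signal had a median of 7 lower and 15 higher. The match did not include the ERE, and at common ER sites this ratio was 0.357 with an ERE and 2.78 without. How much of the difference from random lists goes with the ERE was not tested. With each gene represented by the site nearest to its TSS, SRC-3 was lower at 6 and higher at 2. In shFbxo22 cells SRC-3 was lower at 3 and higher at 2 of the 35. After division by the ratio at all common ER sites, which was 2.17 in control cells and 0.892 in shFbxo22 cells, the counts were 23 lower and 2 higher in control cells (random medians 13 and 8), and 2 lower and 7 higher in shFbxo22 cells (random medians 2 and 1). The 17 genes included GREB1, CTSD, RARA, XBP1, CCND1, IGFBP4, PDZK1, ADCY9, ABCA3 and CELSR2. IGFBP4 (chromosome 17, 38605063 to 38605113, intron, with an ERE), chosen after its values were seen, had 12.5 and 1.31 SRC-3 tags per 10 M in control cells and 12.5 and 14.2 in shFbxo22 cells. For luminal transcription factors (19 with a site) the control counts were 2 lower and 10 higher. After the same division, which moves all genes alike, they were 5 lower and 3 higher. Matched random lists had medians of 3 lower and 9 higher before the division and 5 and 5 after it, so these counts were near those of other genes. Immediate early and AP-1 genes (11 with a site), which share EGR3 with the estrogen response list, had 3 lower and 2 higher (random medians 1 and 5). After the division they had 7 and 0 (random medians 3 and 3), and at the site nearest to the TSS 2 and 2. Cell-cycle genes (9 with a site), which share CCND1 with it, had 1 lower and 2 higher (random medians 0 and 3). After the division they had 3 and 1 (random medians 0 and 2), and at the site nearest to the TSS 0 and 1.

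ER at the same sites of the 35 estrogen response genes was higher in shFbxo22 than in control cells under E2 at 27 and lower at 0, where matched random lists had a median of 25 higher. After division by the common-site ratio of 2.06 it was higher at 7 and lower at 4 (random medians 5 and 3). With E2+4OHT over E2 in control cells it was higher at 14 (random median 20) and lower at 0, but higher at 2 and lower at 10 after division by 1.87, which moves all genes alike (random medians 5 and 7). In shFbxo22 cells it was lower at 23 (random median 19) and higher at 1, and lower at 17 and higher at 4 after division by 0.646 (random medians 9 and 5). Over all 10129 genes with a site, SRC-3 with E2+4OHT over E2 was lower at 519 and higher at 3692 in control cells, and lower at 471 and higher at 131 in shFbxo22 cells. After division by the common-site ratios of 2.17 and 0.892 it was lower at 1252 and higher at 2019, and lower at 307 and higher at 244. For ER, shFbxo22 over control, the counts were 3284 higher and 72 lower under E2, and 195 higher and 1742 lower under E2+4OHT. After division by the common-site ratios of 2.06 and 0.712 they were 626 higher and 628 lower, and 645 higher and 569 lower.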

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

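All tests in this part were chosen after the result was seen, and no difference between control and shFbxo22 cells was tested, since each condition is 1 library. Several values lay in opposite directions in the 2 backgrounds. ER signal with E2+4OHT over E2 was 1.56 in control and 0.490 in shFbxo22 cells at common ER sites with an ERE, and 1.93 and 0.677 without one. SRC-3 signal at common sites without an ERE was 2.78 and 0.896. ER peak numbers with E2 and E2+4OHT were 12580 and 26690 in control and 23173 and 19879 in shFbxo22 cells, and SRC-3 peak numbers were 1721 and 2515, and 5570 and 2602. A signal outside the listed peaks also stood out: 13382 ER sites had at least 5 SRC-3 tags per 10 M in control cells with E2+4OHT, and 1 of them lay within 500 bp of a peak in that library's own list.

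The first pattern is the low SRC-3 signal at ERE sites in control cells with E2+4OHT. A lower yield of the whole library is argued against by the ratio of 2.78 at sites without an ERE. An exchange with an ER library is argued against by the correlations, at most 0.319 with an ER library and at least 0.465 with an SRC-3 library. Another antibody or sample in that library stays open: its best correlation with SRC-3 libraries lay 0.276 below the lowest among the other 3. A loss of SRC-3 from ERE sites under 4OHT that needs Fbxo22, the biological candidate, would be consistent with the ratio of 0.357 in control and 0.904 in shFbxo22 cells, but cannot be told apart from an aberrant library without a repeat, and would be reversed if the cells behind the titles were exchanged.

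The second pattern is that the SRC-3 list of control cells with E2+4OHT lacks that library's strongest ER sites. Too few tags at those sites is argued against, because 13381 sites with at least 5 tags were missing while the highest listed peak had 5.25. Removal of peaks against a control profile resembling this library is a candidate explanation: in the other 3 SRC-3 lists, at least 65.6% of ER sites with 5 own tags or more were listed where this library was under 0.25 of the own signal, and at most 0.537% where it was at least as high. No biological explanation was tested for the composition of the list. The SRC-3 peak lists and their overlaps may therefore partly reflect such a filter, which the notes do not record. Each of the other SRC-3 lists also held only 9.10% to 9.81% of the ER sites with at least 5 own tags per 10 M.

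The third pattern is the opposite order of ER signal and peak number. Greater depth as the source of more peaks is argued against. All 3 other ER libraries had fewer total tags than the library with the fewest peaks. The median ER signal at common ER sites fell as library totals rose. It was 7.78, 7.07, 5.03 and 3.78 tags per 10 M at 32.4, 32.6, 37.0 and 39.2 M, and what links these was not tested. For shFbxo22 against control under E2, the ratio was not shared by all ER sites. It was 0.880 (0.762 to 1.07) at satellite ER sites and 2.06 (2.02 to 2.11) at common ER sites. Tags were scaled to library totals, so a factor on all tags cancels. This contrast therefore cannot decide about a difference in immunoprecipitation yield. One factor for 4OHT against E2 does not cover the difference by ERE. The ratio at ERE sites was 0.807 of that at other sites in control and 0.724 in shFbxo22 cells. This difference goes the same way in both cell types, so it cannot decide whether a factor per library produced the opposite order. One factor on ER-bound tags over a background, as from immunoprecipitation yield, could explain the E2 difference, and so could a higher ER occupancy. There the ratio at sites with an ERE was 1.02 times that at sites without, while with E2+4OHT it was 0.918 (0.877 to 0.988). A biological effect of 4OHT on ERE sites also stays open, and none of these was tested with a second library.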

How the results depend on the processing

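The settings for list overlap, location and gene-list distance were planned, and those for signal ratios and for the strongest site per gene were chosen after the results were seen. No paired analysis was possible because each group has 1 library, and no replicate was left out. The motif alternatives (central 100 bp, 0 mismatches) were not run, since no genome of the files' build was at hand. In the lists of overlap shares below, values are percents of the first list in the order: shFbxo22 against control for ER with E2, ER with E2+4OHT, SRC-3 with E2, SRC-3 with E2+4OHT; 4OHT against E2 for ER in control, ER in shFbxo22, SRC-3 in control, SRC-3 in shFbxo22; SRC-3 on ER in control with E2, control with E2+4OHT, shFbxo22 with E2, shFbxo22 with E2+4OHT.

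With 50% reciprocal overlap the shares were 44.9, 28.7, 15.7, unmoved, 44.5, 30.7, 0.174, 5.80, 25.04, 0.318, 8.92 and 12.8, lower by construction, as fewer overlaps count. With midpoints within 500 bp they were higher by construction: 83.8, 62.4, 29.1, 0.596, 83.8, 65.2, unmoved, 10.8, 42.0, 1.83, 19.6 and 27.9. With the upper 50% of each list by score they were 82.8, 57.6, 40.7, unmoved, 80.5, 58.1, unmoved, 14.1, 57.2, 0.239, 22.4 and 32.5. With both lists at the shorter length they were 60.0, 56.4, unmoved, unmoved, 56.5, 52.8, unmoved, 16.3, 18.6, 0.0398, 10.6 and 11.2. Without dense bins only SRC-3 on ER in control cells with E2 moved, to 38.4. Unmoved means within the counting interval of the reported share. For these shares the cause was not tested beyond what the construction shows.

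These settings do not test the low shares of the SRC-3 list of control cells with E2+4OHT, because that list lacks 13381 of the 13382 ER sites with at least 5 own tags whatever overlap is asked for. For ER no order of the shares is drawn between control and shFbxo22 cells, because list length sets these shares and the reverse shares go the other way (30.8% in control and 54.9% in shFbxo22 cells).

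The promoter share in the upper 50% of each list was 2.31% for ER in control cells with E2+4OHT, and 2.62% and 2.35% in shFbxo22 cells with E2 and E2+4OHT. The other 5 libraries, and all 8 without dense bins, stayed within their intervals. The cause was not tested. Within 10 kb of the TSS, the estrogen response list had 9 and 1 members near SRC-3 peaks in control cells with E2 and E2+4OHT, and 14 and 11 in shFbxo22 cells, fewer by construction. At any distance the control list with E2+4OHT had 5. The ER counts of this list were within 1.5 times the reported ones under all settings, and at equal list lengths so were its SRC-3 counts. The other gene lists depended more on these settings: 42 of 64 counts moved by over 1.5 times, or to or from 0, within 10 kb, 10 of 64 at any distance and 15 of 48 at equal lengths. Within 10 kb the ER counts of amplified-region genes were 2 and 7 in control cells with E2 and E2+4OHT, and 6 and 3 in shFbxo22 cells.

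No signal ratio whose interval excluded 1 changed direction with ER sites in 2 or more lists, with as many sites chosen by mean ER tags, without dense bins, without satellites or with the ratio of means. Moves beyond the interval came with sites in 2 or more lists (9 of 16 ratios), with means (7 of 16) and with sites by mean ER tags (1 of 16). With means the SRC-3 ratio at ERE sites in control cells was 0.650 in place of 0.357, and the ratio of shFbxo22 over control with E2+4OHT was 1.44 in place of 2.69. Division by the common-site ratio moved 27 of 32 counts per gene list by over 1.5 times or from 0, and the site nearest to the TSS moved 21, of which the lower SRC-3 calls of estrogen response genes in control cells were 6 in place of 17. The cause was not tested.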

Other observations

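Values in this part come from comparisons chosen after the data were seen. The 374 ER sites in satellite sequence, where reads of near-identical copies collapse, included 4 of the 10 named peaks shared by both ER lists under E2, and their removal left the signal ratios at common ER sites within their intervals. The numbers in the peak names had gaps, and what the gaps mean was not tested: the listed peaks were 30.8% to 45.1% of the highest peak numbers in the ER lists and 2.55% to 8.94% in the SRC-3 lists.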
